A study of Homo sapiens with 6 samples.

How the data were processed

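RNA from cultured human brain microvascular endothelial cells was measured on 1-colour Agilent whole-genome expression arrays, with 3 wells given marinobufagenin (MBG) and 3 wells given the dimethyl sulfoxide vehicle. Per the labels' protocols, the cells were purchased primary cultures, brought to 80% confluence, kept in 0.5% serum for 24 h, and then returned to medium with 10% serum together with the treatment. Groups and replicate numbers were taken from the sample titles. The labels describe replicate wells and name no separate donors, so p-values measure the spread between these wells, which may be technical.

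The deposited scanner files hold Cy3 intensity per spot on a linear scale, 1 array per file. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.1.1; the submitters' processing notes name version 9.1 of the same software. Per the file headers, the processed intensity is background-subtracted and spatially detrended, low values are replaced by a small positive value, and no normalization between arrays was applied. A deposited value table of 29292 probes holds log2 values. Its scale and centring, which no source used here states, were worked out by setting each column against the scanner values: log2 processed intensity, quantile-normalized between arrays and centred on each probe's median over the 6 arrays, correlated with the columns at 0.992 to 0.999. The column medians were 0.0151, 0.0216 and -0.0172 for vehicle replicates 1 to 3 and 0.0329, -0.0194 and -0.0791 for MBG replicates 1 to 3. Direction followed the sign of the log2 signal, and how its probes were selected stayed unknown. Other deposited columns used were the median spot and local background intensity and the software's 0/1 flags per spot for signal well above background, outliers and saturation.

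Values were log2 of the processed signal minus the log2 of each array's 75th percentile. Control spots were left out, outlier-flagged spots were set to missing (0.763% to 2.72% of spots per array), and the 10 spots of each of 999 repeated probes were averaged. No probe value was saturated. The array carried 34127 probes that are not controls. The scanner files give no gene names, so accessions without their version were matched to a RefSeq gene table of assembly GRCh38.p14, used for names only. This named 25715 probes, and the other 8412 kept their accession or probe name. Probes well above background on at least 3 of the 6 arrays were kept, with a missing value counted as not above background. Shares of detected genes left out arrays on which a gene had no value. The probe with the highest mean over all 6 arrays stood for its gene, which gave 17986 tested features, of which 14232 carried a symbol. Of 26 named genes with more than 1 tested probe, 15 had probes of both signs: SLC8A1, CDH2, CXCL1, NOTCH1, LAMA4, FHL2, PLK1, CHAC1, HSP90AA1, HSP90AB1, AKR1C1, LSS, RPS23, SYT1 and MUC1. XIST and Y-linked genes are not reported.

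Differences were tested with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes moderation, two-sided, Benjamini-Hochberg adjustment over all tested features, threshold 0.05). Intervals are 95% confidence intervals of the same model. Of the 32 gene lists fixed before the data were examined, the 30 with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. List tests left out 579 features with a missing value. The rule for named genes, also fixed before the data were examined, took 12 genes per direction past the threshold with non-overlapping groups, ranked by size, filled up with the genes of smallest unadjusted p where fewer passed. It added up to 4 members of each list with the smallest p, and always ATP1B1 and ATP1B3. A further gene that the rule takes is not reported here. A gene whose probe was well above background on 0 arrays of a group would be given only as a bound; each named gene was above background on at least 1 array of each group. Differences of genes above background on only some arrays include values at or near the other arrays' floor.

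Each array's slide was read from the file headers, without reporting its number. Slide 1 held vehicle replicate 1 and MBG replicates 1 and 2. Slide 2 held vehicle replicates 2 and 3 and MBG replicate 3. Since both slides held both groups, differences were also fitted with slide as a block and computed within each slide. On slide 1 vehicle lay at position 1 and MBG at positions 2 and 3. On slide 2 vehicle lay at positions 1 and 2 and MBG at position 3. Within slides, position and treatment can thus hardly be separated, and the slide block does not remove this. No 2 arrays shared an identical value at any spot. Whether equal replicate numbers pair the wells was checked by correlating deviations from the group means, and the numbers were not treated as pairs. Alternatives were quantile normalization, normexp background correction, the deposited value table, other filters on dim probes, other rules for probes of a gene, an intensity trend, array weights, replicate and slide blocks, and leaving out each array. Normexp was run on the median spot signal, with an offset of 50, because the files used here have no mean spot signal column.

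The fit was tested on simulated data for MBG against vehicle: 21237 probes with the measured means and the moderated spreads, and 200 changed probes. It recovered 0% of the 50 probes changed 1.5-fold, 18% of those changed 2-fold, 62% of those changed 4-fold and 84% of those changed 8-fold, with 2 false calls. A list of 25 probes shifted by 0.5 on the log2 scale was called among 30 simulated lists. Simulated probes varied independently, unlike real genes. Their spread was the same on every array, with no slide difference and no raised floor on MBG replicates 2 and 3. The shares recovered are thus not those to be met on the real arrays, above all for dim genes. The number of arrays limits the precision: the median standard error of a log2 difference was 0.183, and 0.123 for genes well above background on all 6 arrays.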

Results

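Marinobufagenin is a cardiotonic steroid that binds the sodium pump, the Na,K-ATPase. Gene expression was measured in primary human brain microvascular endothelial cells, the cells that line the small vessels of the brain, after 12 h with 10 nM MBG (3 wells) or with vehicle (3 wells). Values are log2 signals relative to each array's 75th percentile, and differences are MBG minus vehicle. The arrays differed in signal over background. Probes well above background made up 62.3%, 70.0% and 64.9% on vehicle replicates 1 to 3 and 70.5%, 42.7% and 22.4% on MBG replicates 1 to 3. The software's grid check failed on MBG replicate 3.

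**Figure D1:**
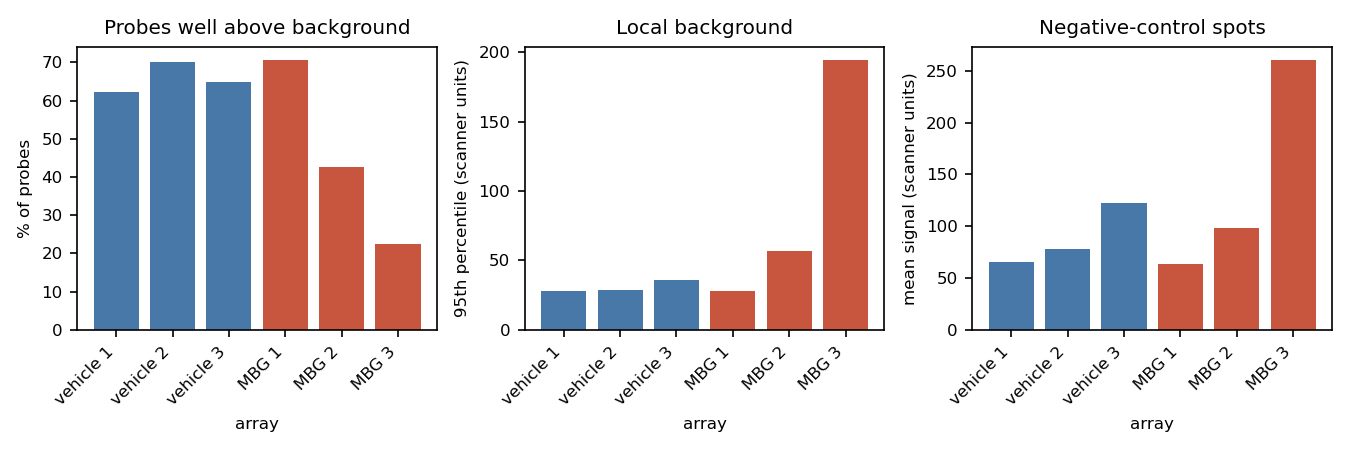
Bars give, for each array (x axis), the percent of probes well above background, the 95th percentile of the local background and the mean signal of negative-control spots, both in scanner units (blue, vehicle; red, MBG). MBG replicate 3 had 22.4% of probes well above background and a 95th percentile of local background of 194, against at most 36 on the vehicle arrays.

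The comparison asks which genes MBG changes in these cells. No gene passed the threshold in either direction: 0 of 17986 features were higher and 0 were lower by limma with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 259 higher and 340 lower features, 599 in all, where 899 would be met by chance. The smallest adjusted p was 0.0652. With slide as a block the counts past the threshold were also 0 and 0, with 1184 higher and 597 lower at an unadjusted p under 0.05. The groups did not overlap for 11.4% of the features, where chance gives 10%. The 95% interval lay within a 2-fold change either way for 65.5% of all features and for 94.7% of those well above background on all 6 arrays. Of the features, 11787 were detected on 3 to 5 arrays only. Their values on the other arrays can lie at or near the floor, so their intervals need not hold the true change.

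The genes nearest to the threshold on the higher side were dim. FRAT1, a GSK3-binding protein of the Wnt pathway, was at -4.59 ± 0.08 (SD, n = 3) with vehicle and -2.47 ± 0.15 (SD, n = 3) with MBG. Its difference was 2.12 (SE 0.12, limma adjusted p = 0.0652), with 2.20 within slide 1. The 2.09 within slide 2 is not an exact difference, since FRAT1 was not above background on MBG replicate 3, the only MBG array there. ARVCF, a catenin of the p120 family, differed by 2.85 (SE 0.21, limma adjusted p = 0.0759). CAPN6, a member of the calpain family, differed by 2.28 (SE 0.17) and EBF1, a transcription factor, by 3.73 (SE 0.28), both at a limma adjusted p of 0.0759. CELSR3, a cadherin of planar cell polarity, differed by 1.69 (SE 0.15) and CAMK4, a calcium/calmodulin-dependent kinase, by 2.20 (SE 0.21). The other 6 were ADH4 at 4.60, OR4Q3 at 2.42, CELA3A at 1.67, C19orf33 at 1.33, TMEM192 at 1.92 and H1-9P, a pseudogene, at 3.77. All 12 were well above background on MBG replicate 1, 10 were on MBG replicate 2 and 0 were on MBG replicate 3. On the vehicle side 6 of the 12 were above background on all 3 arrays, while ADH4, EBF1, H1-9P and CAPN6 were on 1 array and ARVCF and CAMK4 on 2. The differences of all 12 are not exact, since the value of MBG replicate 3 enters each MBG mean and SD. These sizes depended on the setting. With a common floor on all arrays, chosen after seeing the data, FRAT1 differed by 0.13, CAPN6 by 0.08, CAMK4 by 0.13 and EBF1 by 0.49. That floor, -2.58, is the floor of MBG replicate 3 and lies above every vehicle value of these genes. Their smaller differences thus follow from the setting and do not test the true sizes. C19orf33 differed by 0.07 with quantile normalization. Of the 24 leading genes of both sides, 9 had an unadjusted p under 0.05 with quantile normalization and 9 in the deposited table. The vehicle means of the 12 higher-side genes lay between -6.37 and -3.61. With slide as a block 0 of the 12 passed (smallest adjusted p = 0.151). FRAT1 passed when dim probes were kept (adjusted p = 0.0427). FRAT1 and CELSR3 passed when MBG replicate 3 was left out and probes had to be detected on the 5 other arrays (adjusted p = 0.0214 for both). The fit without MBG replicate 3 leaves only vehicle arrays on slide 2, so treatment and slide are partly mixed in it. With array weights, a fit that MBG replicate 1 dominates, 11 named genes passed, among them FRAT1, ARVCF, CAPN6, EBF1 and ADH4.

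On the lower side the smallest p belonged to MAU2, a subunit of the cohesin loader. It was at 1.40 ± 0.04 (SD, n = 3) with vehicle and 0.61 ± 0.09 (SD, n = 3) with MBG, a difference of -0.79 (SE 0.10, limma adjusted p = 0.325), and it was well above background on all 6 arrays. Within slides it differed by -0.79 and -0.75. FBXO11, an F-box protein, differed by -0.68 (SE 0.11), NFIX, a transcription factor, by -0.79 (SE 0.14), and BAZ1B, a chromatin remodelling protein, by -0.61 (SE 0.12). SLC37A4, the glucose-6-phosphate transporter of the endoplasmic reticulum, differed by -0.49 (SE 0.09) and STX1A, a SNARE protein, by -0.49 (SE 0.11). The remaining genes were WASH5P at -0.75, AGER at -0.54, CCDC172 at -0.64, RRH at -0.53, IL17RE at -0.84 and TMEM191B at -0.47. Only 2 of the 12 were above background on MBG replicate 3, so the sign within slide 2 was measured above background for these alone, and 0 of 12 passed with slide as a block (smallest adjusted p = 0.387). MAU2 alone of the 12 passed with array weights (limma adjusted p = 0.0240), a fit that MBG replicate 1 dominates.

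**Figure D2:**
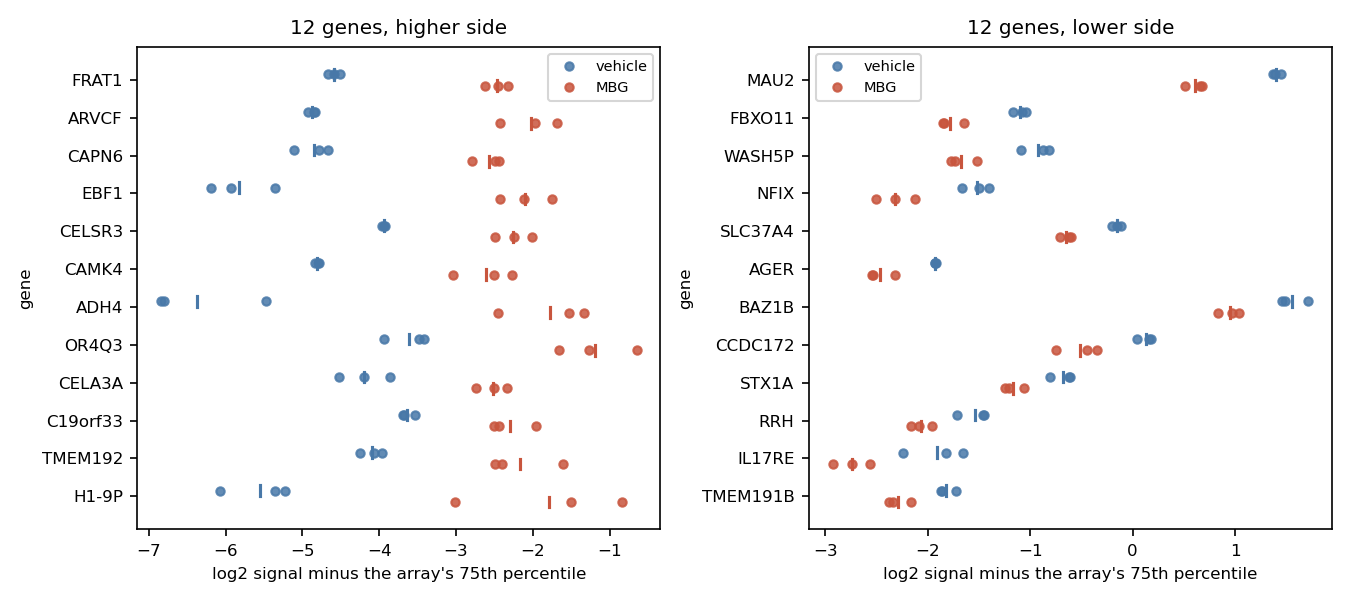
Points are single arrays and short vertical lines are group means (blue, vehicle; red, MBG; n = 3 each); the x axis is the log2 signal minus the array's 75th percentile and the y axis lists the 12 genes of smallest p on each side. The higher-side genes had vehicle means between -6.37 and -3.61, and no gene passed the threshold.

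Of the 30 gene lists tested, 0 passed with camera at the preset correlation, 0 with an estimated correlation and 0 with fry. With slide as a block 0 lists passed (smallest adjusted p = 0.0829, pericyte or smooth muscle markers). Beside that, 0 genes passed in any of the 32 lists when p was adjusted over the list alone. The members given below are among those with the smallest p in their list, except ATP1B1 and ATP1B3, which were named in advance, and none passed the threshold. Of the 149 named genes, 81 were not above background on MBG replicate 3, the only MBG array on slide 2, so that their values within slide 2 are not exact differences. Without that array 33 differences moved by over 1.5 times with the same sign and 5 changed sign. Under the slide block 19 moved by over 1.5 times with the same sign and 2 changed sign.

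The subunits of the sodium pump, the target of MBG, showed no difference past the threshold. Of 13 tested members, 6 were higher and 7 lower, with a median of 0.00 (camera adjusted p = 0.821) and medians of -0.04 within slide 1 and 0.21 within slide 2. ATP1B1 differed by 0.07 (interval -0.19 to 0.33) and ATP1B3 by 0.00 (interval -0.28 to 0.28), the latter over 2 vehicle wells. FXYD6 and FXYD3, small regulatory subunits, differed by 0.91 (SE 0.52) and 0.68 (SE 0.46), but by 0.37 and 0.19 without MBG replicate 3, on which neither was above background. ATP1A4 differed by -0.18 (SE 0.11) and FXYD7 by 0.58 (SE 0.64), which was 0.92 with slide as a block and turned to -0.12 without MBG replicate 3, on which it was not above background. Among ion transport genes, 11 were higher and 16 lower (camera adjusted p = 0.684). ORAI1, the pore of the store-operated calcium channel, differed by -0.40 (SE 0.16), and SLC8A1, the sodium-calcium exchanger, by -1.23 (SE 0.59), with -2.41 within slide 1. It was above background on 1 MBG array, and its 0.27 within slide 2 rests on a value near the floor of MBG replicate 3. Another SLC8A1 probe went the other way, at 0.57.

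Signalling lists were likewise divided. Of the immediate-early and AP-1 genes, 14 were higher and 10 lower (camera adjusted p = 0.821), with JUN at 0.20 (SE 0.14) and SIK1, a salt-inducible kinase, at -0.29 (SE 0.14). Of the MAPK/ERK feedback genes, 7 were higher and 13 lower (camera adjusted p = 0.797), with the phosphatase DUSP4 at -0.34 (SE 0.13) and SPRY1 at -0.33 (SE 0.22). TGF-beta, BMP and mesenchymal transition genes numbered 14 higher and 15 lower (camera adjusted p = 0.821), with SMAD3 at -0.21 (SE 0.09) and SNAI2 at 0.33 (SE 0.16). For YAP/TAZ and SRF targets the counts were 7 and 17 (camera adjusted p = 0.749), with the calponin CNN2 at -0.64 (SE 0.20) and FHL2 at 0.30 (SE 0.12). Angiogenic growth factor and Notch genes gave 14 higher and 11 lower (camera adjusted p = 0.821), with PGF at -0.56 (SE 0.35) and EFNB2 at -0.22 (SE 0.12).

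None of the endothelial, barrier and vascular lists passed the threshold. Of 18 tested endothelial identity genes, 9 were higher and 9 lower (camera adjusted p = 0.821). CDH5, the endothelial cadherin, differed by -0.58 (SE 0.38), CLEC14A by 0.38 (SE 0.15) and NOS3, the endothelial nitric oxide synthase, by -0.41 (SE 0.29). CDH5 differed by -0.30 and NOS3 by -0.22 with slide as a block, and NOS3 had opposite signs within slides (0.19 and -0.63). Of 33 endothelial identity genes on the array, 11 had no probe well above background on any of the 6 arrays. Junction genes numbered 14 higher and 7 lower (camera adjusted p = 0.962), with the gap junction gene GJA1 at 0.26 (SE 0.12) and CDH2 at 0.44 (SE 0.22). Blood-brain barrier transporters and receptors split 11 to 11 (camera adjusted p = 0.749). AGER, the receptor for advanced glycation end products, had the smallest limma p adjusted over the list alone (0.0591). Its value on MBG replicate 3, -2.54, was not above background and lay near that array's floor of -2.58. BSG, basigin, differed by -0.35 (SE 0.13). Among leukocyte adhesion, chemokine and NF-kB target genes, 18 were higher and 8 lower (camera adjusted p = 0.821), with CXCL5 at 0.33 (SE 0.13) and ICAM1 at -0.24 (SE 0.12). Vascular tone genes gave 14 and 9 (camera adjusted p = 0.962), with ACE, the angiotensin-converting enzyme, at -0.65 (SE 0.19) and PTGIS, prostacyclin synthase, at 0.46 (SE 0.16). Coagulation and fibrinolysis genes gave 11 and 9 (camera adjusted p = 0.962), with TFPI2 at 0.58 (SE 0.24). Extracellular matrix genes gave 19 and 18 (camera adjusted p = 0.821), with COL6A2 at -0.37 (SE 0.14) and MMP1 at 0.28 (SE 0.16).

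Growth and stress lists gave no call. G2/M genes numbered 15 higher and 14 lower and G1/S genes 12 and 18 (camera adjusted p = 0.821 and 0.811). Of the G2/M list, DLGAP5 was at 0.22 (SE 0.10) and PLK1 at -0.63 (SE 0.30), with another PLK1 probe at 0.27. MCM7, a replicative helicase subunit of the G1/S list, was at -0.25 (SE 0.10). p53 target and apoptosis genes gave 16 and 11 (camera adjusted p = 0.821), with BCL2L1 at -0.46 (SE 0.16). Unfolded protein and integrated stress response genes gave 18 and 8 (camera adjusted p = 0.577). In that list the chaperone HSPA5 was at 0.27 (SE 0.11), and CHAC1 and PPP1R15A, both induced by ATF4, were at -0.41 (SE 0.13) and -0.32 (SE 0.12). Heat shock genes gave 13 and 6 (camera adjusted p = 0.821), with HSPE1 at 0.24 (SE 0.12). NRF2 and oxidative stress genes gave 14 and 12 (camera adjusted p = 0.821). NQO1, a quinone reductase, was at -1.43 ± 0.14 (SD, n = 3) with vehicle and -0.66 ± 0.34 (SD, n = 3) with MBG, a difference of 0.77 (SE 0.20, limma adjusted p = 0.919), with 0.95 within slide 1 and, on an array where it was not above background, 0.44 within slide 2. AKR1C1 differed by 0.30 (SE 0.11). Cholesterol genes gave 16 and 8 (camera adjusted p = 0.821), with FDPS at 0.22 (SE 0.12). Interferon response genes gave 15 and 12 (camera adjusted p = 0.821), with RIGI, an RNA sensor, at -0.32 (SE 0.10) and IFI44 at 0.44 (SE 0.21).

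The list closest to the threshold was the mitochondrial respiratory chain. Of its 30 members, all of them well above background on all 6 arrays, 24 were higher and 6 lower, with a median of 0.09 (camera adjusted p = 0.0881). Of all genes detected on all 6 arrays, 60.6% were higher, with a median of 0.04. COX5A and COX4I1, subunits of cytochrome c oxidase, differed by 0.22 (SE 0.10) and 0.19 (SE 0.09). Of 36 cytosolic ribosomal protein genes, 27 were higher and 9 lower, with a median of 0.08 (camera adjusted p = 0.437) and RPL38 at 0.21 (SE 0.09). Hypoxia and glycolysis genes gave 19 and 8 (camera adjusted p = 0.437), with BNIP3L, a mitophagy receptor, at 0.37 (SE 0.11). Without MBG replicate 3 the mitochondrial and ribosomal lists passed (adjusted p = 0.00162 for both). Without vehicle replicate 1 these passed (adjusted p = 0.0139 for both) together with the hypoxia list (adjusted p = 0.00445). With an estimated correlation the adjusted p of these lists was 0.835 without MBG replicate 3 and 0.974 without vehicle replicate 1. Leaving out MBG replicate 3 leaves slide 2 with vehicle arrays only. Leaving out vehicle replicate 1 leaves slide 1 with MBG arrays only. In both fits treatment is thus partly mixed with the slides. With slide as a block the adjusted p was 0.557 for the mitochondrial list and 0.985 for the ribosomal and hypoxia lists. Within slides the mitochondrial median was 0.10 and 0.05.

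Markers of other cell types did not pass either. Of 11 tested pericyte or smooth muscle genes, 2 were higher and 9 lower, with a median of -0.14 and a mean of 0.09 (camera direction down, adjusted p = 0.577). RGS5 was at 1.68 (SE 0.74) and ITGA7 at -0.42 (SE 0.21). With slide as a block and detection on all 6 arrays, a setting chosen after seeing the data, the 7 members left passed (adjusted p = 0.00554), and the adjusted p was 0.932 with an estimated correlation. Fibroblast genes gave 4 higher and 8 lower (camera adjusted p = 0.821), with COL1A2 at -0.15 (SE 0.11) and a median of -0.07 against a mean of 0.02. Neuron genes gave 4 and 3 (camera adjusted p = 0.900), microglia and leukocyte genes 4 and 5 (camera adjusted p = 0.577), and epithelial genes 3 and 4 (camera adjusted p = 0.821). FCER1G of the leukocyte list differed by -0.36 (SE 0.12). Astrocyte and lymphatic endothelial lists had 3 tested members each and were not tested.

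**Figure D3:**
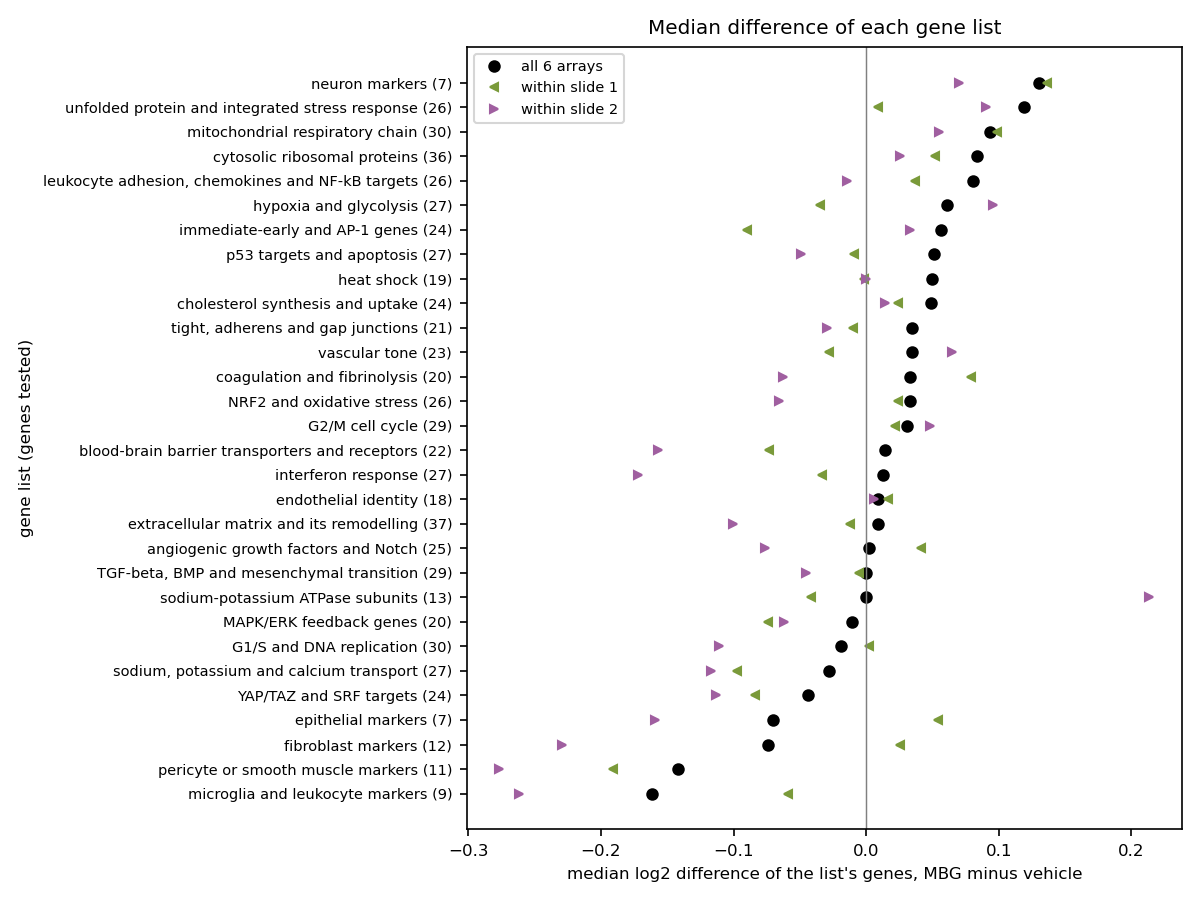
Each row is a gene list with its number of tested genes; the x axis is the median log2 difference, MBG minus vehicle, over all 6 arrays (black) and within slide 1 and slide 2 (triangles). The mitochondrial list had a median of 0.09 over all arrays and 0.10 and 0.05 within slides, and 0 lists passed the threshold.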

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

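Values outside the gene comparison were higher on some MBG arrays than on every vehicle array. The 95th percentile of the local background was 57 on MBG replicate 2 and 194 on MBG replicate 3, against 36 on the highest vehicle array. The mean signal of negative-control spots was 260 on MBG replicate 3, against 122 on the highest vehicle array. Both MBG arrays lay at the third position of their slide, so position and treatment cannot be separated for them.

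Of the tests below, those on the raised floor, on stray spots, on the slides and on the counts of genes and lists past the threshold were chosen after related values had been seen. When dim probes were kept, 21 of 27713 features were called higher with MBG and 0 lower, while the filtered comparison called 0. Of the 21, 18 were above background on 0 vehicle arrays, 21 on MBG replicate 1, 15 on MBG replicate 2 and 0 on MBG replicate 3. A raised floor on MBG replicates 2 and 3 stays open. That 15 of the 21 were above background on 2 or more MBG arrays does not decide, since a gene had to match the floor of MBG replicate 3 on the other MBG arrays to be called. With every array raised to a common floor 0 of the 21 stayed called, as values under that floor are set equal. Stray bright spots stay open too: MBG replicate 1 held 132 probes standing over 3 log2 units above the other low-background arrays, 0.663 times the 199 of vehicle replicate 3, which gives no reason for calls on the MBG side alone. On MBG replicate 3, where 0 of the 21 were above background, the floor alone sets the value, and a response to MBG stays open and untested.

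Fewer genes had an unadjusted p under 0.05 (599) than the 899 met by chance. The count depended on single arrays: leaving out 1 array gave from 204 (without vehicle replicate 2) to 1196 (without MBG replicate 3). Without MBG replicate 3, slide 2 holds vehicle arrays only, so the 1196 may include differences between the slides. Deviations of arrays from each gene's mean correlated at 0.164 on average within slides and -0.423 between slides, a gap of 0.587, and a difference between the slides may have inflated the spread. This stays open as 1 possible source of the low count. Those correlations came from genes detected on all 6 arrays, of which 139 of 6199 had such a p in the comparison of all features, against 310 by chance. Fitted on their own, also without a slide term, 6277 features detected on all 6 arrays gave 454 against 314 by chance. Over all features, counts without a slide term were also 938 with an intensity trend, 929 with a common floor and 1823 with normexp. Other such counts stayed under the 899 by chance: 736 with quantile normalization, 700 in the deposited table and 545 with the mean of a gene's probes. The intensity trend leaves the values and the slides as they are and changes only how spreads are shared between genes. With its count at 938, the low count of 599 did not come from the slides alone. How spreads are pooled over genes also entered it. Of the 10 splits of the 6 arrays, the one that follows the slides gave 3134 genes at an unadjusted p under 0.05 and 367 past the threshold, several times the real split, which points to a structure of the arrays by slide. With slide as a block the real labels gave 1781 such genes. Of the 9 ways to place the labels within slides, 2 gave as many, the other reaching 2612. Both have MBG replicate 3 as the only array of its label on slide 2. The remaining placement of that kind gave 564, and the highest of the others gave 733. A treatment difference, position on the slide, chance and the state of MBG replicate 3 cannot be told apart with 9 placements.

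Splits of 3 against 3 arrays are too few for a share under 0.05. With a real count of 0, every split gives as many by construction: 10 of the 10 splits for genes past the threshold, with a highest other value of 367, and 10 of the 10 for lists, with a highest other value of 7. For genes at an unadjusted p under 0.05, 2 of the 10 splits gave as many as the real 599, the highest other value being 3134.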

How the results depend on the processing

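The settings with a common floor, without MBG replicates 2 and 3 together, with detection on the 5 arrays other than MBG replicate 3, and with slide block plus detection on all 6 arrays were chosen after seeing the data. The counts of genes past the threshold, 0 higher and 0 lower, were the same under most settings. They moved to 21 higher when dim probes were kept, to 22 higher and 4 lower with array weights, and to 4 higher without MBG replicate 3 when detection was required on the 5 other arrays. The array weights rest on MBG replicate 1 at a weight of 24.2 against 0.112 for MBG replicate 3, so that 1 array dominates that fit; the cause of the other moves was not tested. Leaving out each array in turn gave 0 to 0 genes higher and 0 to 0 lower. Whether replicate numbers pair the arrays was not decided. Deviations of equal numbers correlated at 0.47, -0.13 and 0.36, and replicates 1 and 3, not 2, of the vehicle correlated best with their own number. Arrays of replicates 1 and of replicates 3 shared a slide, while those of replicates 2 did not, so pairing and slide cannot be told apart. With the replicate block, 0 genes were higher, 0 lower and 0 lists passed, with 517 genes at an unadjusted p under 0.05, so that the block changed no call.

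The count of lists past the threshold, 0, moved to 3 when dim probes were kept, to 1 with an intensity trend (the mitochondrial list), to 8 with array weights (among them leukocyte adhesion, chemokines and NF-kB targets), to 5 without MBG replicates 2 and 3 together and to 1 with slide block plus detection on all 6 arrays. Without 1 array it ranged from 0 to 3, with 2 lists without MBG replicate 3 and 3 without vehicle replicate 1. At an estimated correlation these calls were lost (adjusted p = 0.835 and 0.974), as was that with slide block plus detection on all 6 arrays (0.932). The cause was not tested. Leaving out MBG replicate 3 or vehicle replicate 1 leaves 1 slide with a single group. Over 149 named genes and 2777 gene values under other settings, 2689 kept their sign without passing, 74 changed sign without passing, 14 passed with the same sign, and 0 passed with the other sign. Of the 14, 11 came with array weights. At an unadjusted p under 0.05 the split was 259 higher and 340 lower, but 141 and 595 with quantile normalization, 105 and 1718 with normexp, and 136 and 564 in the deposited table. Quantile normalization moved the median difference of all genes from 0.03 to -0.10. Genes detected on fewer arrays were measured less precisely: the median standard error was 0.285 for genes detected on 3 to 5 arrays against 0.123 for those detected on all 6.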

Other observations

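All tests below were chosen after the result was seen. The arrays detected a smaller share of endothelial markers than of mesenchymal markers. On the 4 arrays with a low background (vehicle replicates 1 to 3 and MBG replicate 1), 17 of 33 endothelial identity genes (51.5%) were well above background wherever they had a value, against 68.7% of all 19659 symbols on the array. PECAM1, with 3 probes, and ERG, EMCN, SOX17, SOX18, TAL1, FLT1, RAMP2, ECSCR, CD93 and MMRN1 were above background on 0 of the 6 arrays. CDH5, VWF, KDR and ICAM2 were above background on 4 arrays, and TEK, NOS3, FLI1 and MMRN2 on 5. All 12 fibroblast genes (100%) were well above background on the 4 arrays, and 8 on all 6. Of 14 pericyte or smooth muscle genes, 11 (78.6%) were above background on the 4 arrays, among them ACTA2, TAGLN, CNN1, DES, NOTCH3 and PDGFRB. These genes were named after their detection was seen. By list, detection was 30% for astrocyte, 37.5% for lymphatic endothelial, 60% for neuron, 60% for epithelial and 90% for microglia and leukocyte genes. Detection cannot by itself name the cells present, since leukocyte genes were detected at a higher share than pericyte or smooth muscle genes.

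A candidate explanation is that the cultures held mesenchymal cells, or endothelial cells that had taken on mesenchymal expression, which these arrays cannot separate. It needs both mesenchymal lists to be detected at 80% or more, and the lower of them reached 78.6%, so the test did not decide. Detection of the fibroblast list was 48.5 percentage points above that of the endothelial list (Fisher's exact test over genes, two-sided, p = 0.00338). Genes are not independent replicates. The gap argues against arrays too dim for marker genes in general. It does not decide for endothelial genes of low abundance, since the fibroblast list holds genes of high signal, such as COL1A1. Probes that fail to report endothelial genes stay open: of the 11 genes above background on 0 of the 6 arrays, 9.09% have 2 or more probes, and no endothelial reference sample was measured. Among the fibroblast genes, COL1A1 was at 6.72 with vehicle and 6.55 with MBG, COL1A2 at 5.91 and 5.76, and DCN at 5.24 and 5.26; levels of different probes are not comparable and are not ranked. Of the 12 fibroblast genes, 5 are held by another fixed list, such as extracellular matrix, and endothelial cells in culture can express some of them.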
